A study of Mus musculus with 4 samples.

How the data were processed

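The series holds 4 single-cell RNA libraries from mouse bone marrow, 2 from controls and 2 from mutants in which Epas1, the gene for HIF2 alpha, carries floxed alleles and Prx1-Cre is active in limb mesenchyme. Per the labels, marrow was flushed from hindlimb bones of mice aged 12 weeks, cells carrying the Ai14 fluorescent reporter were sorted by FACS, and libraries were made with the 10x Genomics 3' v3 kit. The group of each library was taken from its title, because the genotype written for the controls can also be read as lacking HIF. Whether the libraries came from separate mice is not given in the sources used here, so p-values for single genes and cell shares measure the spread between these libraries. Gene list p-values from camera with a preset correlation set the genes of a list against other genes, and the Fisher exact p counts genes. Neither measures the spread between libraries.

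The deposited matrices hold UMI counts per gene and barcode, with no normalization. Per the submitters' processing notes, reads were processed with Cell Ranger, with no version stated, against mm10, and the filtered matrices were deposited. Each matrix lists 32285 genes with Ensembl identifiers and symbols, and 40 entries share a symbol with another, so genes were tracked by identifier. Coordinates came from the GENCODE M21 annotation of the same build. Each library held 9152 to 13329 barcodes and 55505615 to 83601232 UMIs.

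Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes. Doublets were called per library with Scrublet in scanpy 1.11.5, with an expected rate of 0.008 per 1000 barcodes. The automatic threshold removed 4.27% of cells in control 2, 4.33% in mutant 1 and 4.19% in mutant 2. In control 1 it marked 0.03%, so the expected-rate rule set beforehand was used there and removed 7.33%. Of 43720 barcodes, 34047 cells remained. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen without sex-linked genes and Epas1, and 30 principal components were computed. An exact graph of 15 neighbours was clustered with Leiden at resolution 1.0 (igraph 0.11.9, seed 1), without batch integration. Other versions were python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

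A cluster took the name of a cell class when at least 3 of the class's markers were detected in at least 10% of its cells and lay at least 1 log2 unit above the other clusters, after adding 10 CPM. Several naming choices were made after the clusters were seen. The single mesenchymal cluster was clustered again, and each sub-cluster took the mesenchymal class with more markers among its 10 leading genes, which moved a sub-cluster from LepR-like to osteoblast-like. Sub-clusters with Ptprc, the gene for the pan-leukocyte antigen CD45, in over 50% of cells were set aside as mixed. A pair of clusters led by at least 2 genes of plasmacytoid dendritic cells was left unnamed, and the monocyte class had 0 called genes with them and 1 without them. Neutrophil clusters were also split into mature, immature and promyelocyte stages.

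UMI counts were summed per library over the cells of each class with at least 20 cells in every library, so the library was the unit of replication. Genes were kept with filterByExpr, scaled with TMM and tested by genotype with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, which left 2 residual degrees of freedom, and p was adjusted by the Benjamini-Hochberg method at 0.05. Gene lists were tested with camera from limma 3.58.1 on the same fit, with a preset correlation of 0.01 and at least 3 tested members, and p was adjusted over the lists of a class. Camera with an estimated correlation and fry were run beside it. Shares of cells were compared by a two-sided exact permutation test, which cannot go below p = 0.333 with 2 libraries against 2, and by edgeR on cell counts. Intervals on shares are exact binomial 95% intervals and cover counting error only, as do limits from 3 counts given for a count of 0.

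The cell filter, the clustering settings, the marker and gene lists, the tests, the rule for named genes and the alternative settings first listed below were fixed before the data were examined. In LepR-like cells the rule named Epas1, then up to 10 rising and 10 falling genes with the largest log2 fold change among those with adjusted p under 0.05, a mean log2 CPM of at least 5 and both mutant libraries on the same side of both controls. Markers of non-mesenchymal cell types and sex-linked genes were left out of this choice. Where fewer than 5 genes in a direction passed, the genes with the smallest unadjusted p filled up to 5 and are said not to pass. For each list with a called member, the 3 members with the smallest p were named. Other classes took up to 5 genes per direction by the same rule. Members of lists and cell type markers could also be named.

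The alternative settings were the replicate number as a block, RLE size factors, total counts only, DESeq2 1.42.0, limma-voom, no low-count filter, each library left out, at most 5% mitochondrial UMIs, at least 1000 genes and 2000 UMIs, doublets kept, resolutions 0.5 and 2.0, equal cells per library, removal of markers of other cell types, other list tests and shares of mesenchymal cells only. Alternatives added after the data were seen were the mixed cells included, the LepR-like sub-cluster of lowest UMI count left out, the unnamed cluster resembling neutrophils included, and the neutrophil stages.

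The test was also run on simulated data with 200 changed genes, at the depth and spread of 4 classes. Genes were drawn independently, so shifts shared by many genes of a library were not simulated. For LepR-like cells it recovered 4.48% of genes changed 1.5-fold, 20.9% at 2-fold and 72.7% at 4-fold, with 4 false calls among 69. In the pooled mesenchymal class the last share was 80.3%, with 15 false calls among 87. T or NK-like cells gave 84.8% with 13 false calls among 98, and mature neutrophils 81.8% with 3 among 72.

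Osteoblast-like cells were fewer than 20 in both controls, so neither that class nor its comparison with LepR-like cells was tested.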

Results

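Transcripts were counted in single marrow cells sorted for the Ai14 reporter of Prx1-Cre, in 2 control libraries and 2 libraries from mice with floxed Epas1 alleles. The series asks how loss of HIF2, a transcription factor stabilised at low oxygen, changes the transcriptome of marrow stromal cells. The controls held 55505615 and 65515075 UMIs and the mutants 83601232 and 81038330. After filtering, controls 1 and 2 kept 7147 and 8652 cells, and mutants 1 and 2 kept 10047 and 8201. Median UMIs per kept cell were 4700 and 4299 in the controls and 5482 and 5951 in the mutants, and median mitochondrial shares 0.694% and 2.20% against 1.31% and 1.87%. Xist was between 683 and 1021 CPM in every library and Y-linked genes were at most 0.0247 CPM, so the libraries did not differ in the sex of the mice as far as these genes show.

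Most kept cells carried haematopoietic markers although the sort was on a mesenchymal reporter. LepR-like stromal cells, which express the niche factors Cxcl12 and Kitl and the leptin receptor, numbered 38 and 67 in the controls and 148 and 73 in the mutants. Osteoblast-like cells, with the bone matrix genes Bglap and Ibsp, numbered 14 and 9 against 73 and 37. Sub-clusters carrying stromal genes together with Ptprc, set aside as mixed, numbered 15 and 20 against 114 and 172. LepR-like cells gave 175240 and 336173 UMIs in the controls and 492758 and 301482 in the mutants, which limits genes of low expression.

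Epas1 transcript did not differ detectably between genotypes in LepR-like cells. Epas1 (ENSMUSG00000024140, chromosome 17, 86753700 to 86833410, plus strand, mm10) stood at 967 ± 86.3 CPM in controls and 1082 ± 106 CPM in mutants (SD, n = 2), a log2 fold change of 0.15 (SE 0.23, adjusted p = 0.974). Osteoblast-like cells held 228 and 436 CPM in controls and 243 and 445 CPM in mutants, and no haematopoietic class reached 5 CPM in any library. Which exon is floxed is not given in the sources used here, and a 3' tag can lie outside a deleted part, so this level does not measure the deletion. With the mixed cells included the fold change was -0.35 (adjusted p = 0.503).

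In LepR-like cells, 2 genes rose and 4 fell in the mutants of 5826 tested, while with the replicate number as a block 0 were called. Olfml3, which encodes a secreted olfactomedin-domain glycoprotein, rose from 53.1 ± 5.40 to 300.4 ± 39.4 CPM (SD, n = 2), a log2 fold change of 2.47 (SE 0.31, adjusted p = 0.000583). Limch1, whose product acts on actin and myosin, rose by 1.59 (SE 0.30, adjusted p = 0.0431). Col6a5, a collagen VI chain, had a log2 fold change of -3.41 (SE 0.55, adjusted p = 0.00967), and Kcne4, a potassium channel subunit, one of -2.48 (SE 0.40, adjusted p = 0.00967). Lumican (Lum), a proteoglycan of collagen fibrils, fell by 2.10 (SE 0.40, adjusted p = 0.0433), and Stat5a, a transcription factor of cytokine signalling, fell by 1.46 (SE 0.27, adjusted p = 0.0431). Each of the 6 lay on 1 side in both mutants relative to both controls. Olfml3 (ENSMUSG00000027848) lies on chromosome 3 at 103722222 to 103738001, Limch1 (ENSMUSG00000037736) on 5 at 66745827 to 67057158 and Col6a5 (ENSMUSG00000091345) on 9 at 105856078 to 105960643. Kcne4 (ENSMUSG00000047330) lies on chromosome 1 at 78816758 to 78820028, Lum (ENSMUSG00000036446) on 10 at 97565128 to 97572703 and Stat5a (ENSMUSG00000004043) on 11 at 100859351 to 100885169. Col6a5 was at 74.0 CPM in control 1 and 383 CPM in control 2, from 12 and 121 UMIs, so its control level rests largely on control 2. Kcne4 was likewise at 117 and 361 CPM in the controls, from 19 and 114 UMIs, against 48.8 and 40.5 CPM in the mutants.

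Of genes that did not pass, Alpl, the alkaline phosphatase needed for mineralisation, had a log2 fold change of 1.49 (adjusted p = 0.128). Ncam1, a cell adhesion molecule, had 1.49 and S100a6, a calcium-binding protein, 1.17, both at adjusted p = 0.128. Angptl1, an angiopoietin-like secreted protein, had -1.34 (adjusted p = 0.128). Limch1 and Alpl are also among the leading genes of an osteoblast-like sub-cluster. Olfml3 was higher in every library when osteoblast-like cells were pooled with LepR-like cells than in LepR-like cells alone. In the controls it was at 130 and 98.1 CPM in the pool against 49.3 and 57.0 CPM, and in the mutants at 398 and 357 against 328 and 273 CPM. Whether its rise in LepR-like cells depends on the rule that split them from osteoblast-like cells was not tested. The LepR-like sub-cluster with the lowest median UMI count, 1885, held 13 and 5 cells in the controls and 76 and 21 in the mutants. Without it, with at most 5% mitochondrial UMIs, with the stricter cell filter or with equal cells per library the only call was Olfml3 (1 gene). With the replicate block Olfml3 was lost too. Leaving out control 1, control 2, mutant 1 or mutant 2 gave 43, 31, 18 or 25 calls, of which 6, 2, 5 and 5 were among the 6, and without control 2 those kept were Olfml3 and Stat5a.

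**Figure D1:**
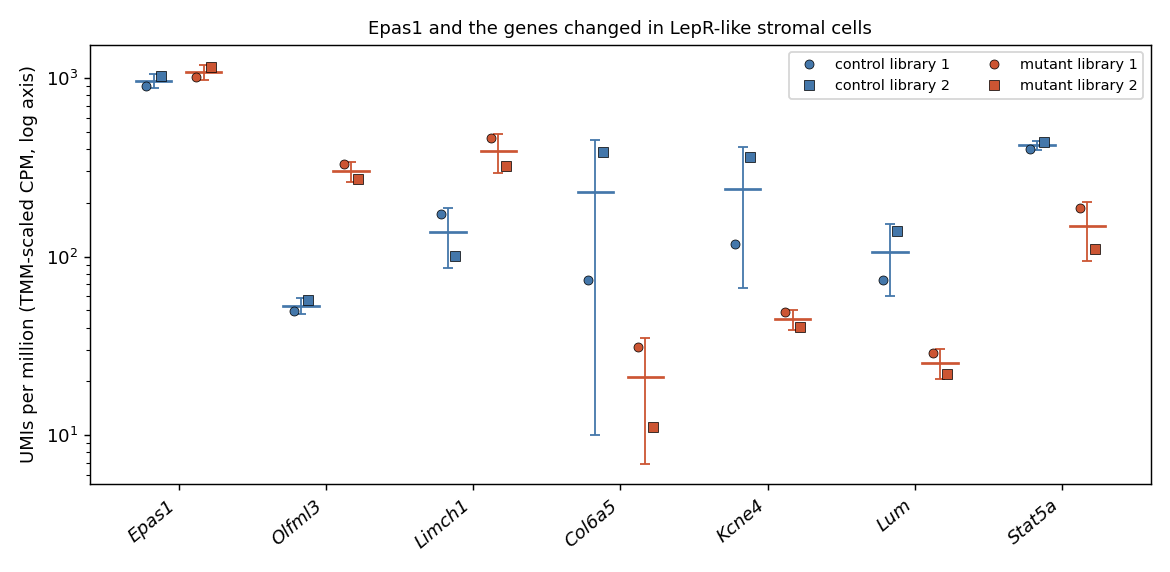
Normalised expression in CPM, on a log axis, of Epas1 and the 6 called genes in LepR-like cells of each library, with points for libraries (circle 1, square 2), a short line for the group mean and whiskers for the SD of 2 libraries. Olfml3 lies at 49.3 and 57.0 CPM in the controls and 328 and 273 CPM in the mutants, while the Epas1 values of the groups overlap.

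Among the gene lists in LepR-like cells, ribosomal protein genes were higher and heat shock, angiogenic and immediate early genes lower in the mutants by camera with its preset correlation. With an estimated correlation all 4 calls were lost, at adjusted p = 0.733 each, and fry gave adjusted p = 0.480 for the first 3 and 0.520 for immediate early genes. Of 77 ribosomal protein genes tested, 74 had a positive log2 fold change, with a median of 0.29 (adjusted p = 3.28e-08). Of 10 heat shock genes, 9 were negative with a median of -0.49 (adjusted p = 0.000166), among them the chaperone genes Dnajb1 at -1.54, Hsph1 at -0.93 and Dnaja1 at -0.78. Of 12 angiogenic factors, 10 were negative with a median of -0.43 (adjusted p = 0.00965), led by Thbs1, an inhibitor of angiogenesis, at -1.51, with Esm1 at -0.53 and the lymphangiogenic factor Vegfc at -0.46. Of 14 immediate early genes, which respond within minutes to stimulation or dissociation, 12 were negative with a median of -0.32 (adjusted p = 0.0334), with Egr1 at -1.56 and Btg2 at -1.31. None of these single genes passed over all genes tested. By camera with the preset correlation, immediate early genes were also lower in 4 of the 7 haematopoietic classes and heat shock genes in 3. With an estimated correlation these calls were lost, at adjusted p from 0.735 to 0.778 for immediate early genes and from 0.527 to 0.735 for heat shock genes. Without control 2 the only list called was ribosomal proteins, with heat shock at adjusted p = 0.243 and angiogenic factors at 0.395. Angiogenic factors were also not called with equal cells (adjusted p = 0.282) or without mutant 1 (0.0525), in a range from 9.04e-06 with mixed cells. Immediate early genes were also not called with the stricter cell filter (adjusted p = 0.328), at resolution 0.5 (0.0856) or without the low-UMI sub-cluster (0.639). With equal cells or mixed cells their test turned upward, uncalled, and over the alternatives their adjusted p ranged from 3.42e-06 without control 1 to 0.935 with equal cells.

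Other lists were not called, with adjusted p from 0.127 for cell cycle (3 tested) to 0.984 for interferon response. Hypoxia response genes outside glycolysis had a median of -0.24, with 12 of 15 negative (adjusted p = 0.307), Vegfa, the main angiogenic factor of that response, at -0.40 and the mTOR inhibitor Ddit4 at 1.34. Glycolysis had a median of 0.12 (9 tested, adjusted p = 0.365). Genes linked to HIF2 gave adjusted p = 0.597 over 8 tested, with the lipid droplet gene Plin2 at -0.60 and the matrix protease Mmp14 at 0.39. Niche factors gave adjusted p = 0.597 over 17 tested, with Cxcl12 at 0.05, Kitl at -0.04 and the chemokines Ccl2 at -2.73 and Ccl19 at -1.03. In adipogenesis, at adjusted p = 0.735 over 14 tested, Adipoq was at -0.70 and Apoe at -0.77, and in osteogenesis, at adjusted p = 0.365 over 12 tested, Col1a1 was at 1.09. The extracellular matrix list (25 tested, adjusted p = 0.782) held the called Lum, with Mgp, an inhibitor of calcification, at 1.29 (adjusted p = 0.157) and Thbs1 at -1.51 (adjusted p = 0.253), neither passing.

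The remaining lists gave adjusted p = 0.284 for Wnt signalling and for mitochondrially encoded genes, 0.355 for inflammatory cytokines, 0.165 for the nuclear-encoded respiratory chain, and 0.597 for TGF-beta and BMP signalling, Notch signalling and cholesterol synthesis. Antioxidant and iron handling gave 0.834 and the unfolded protein response 0.969. Chondrogenesis had too few tested members. Median and test differed in sign for adipogenesis, osteogenesis, interferon response and the unfolded protein response, and the mean and the test for adipogenesis and interferon response. Adjusted over the list alone, 2 heat shock genes (Dnaja1 and Dnajb1), 2 niche factors (Ccl2 and Ccl19) and 2 matrix genes (Lum and Thbs1) were lower. So adjusted, Thbs1 was lower among angiogenic factors, Ccl2 among inflammatory cytokines and Bst2 in the interferon list. Alpl and Col1a1 were higher in osteogenesis, and Ddit4, Mgp, Sfrp1, Creld2 and Stmn1 were each the 1 higher gene of the hypoxia, matrix, Wnt, unfolded protein and cell cycle lists. Other lists had 0 such genes. This adjustment does not allow for the number of lists. Of the genes named for it here, only Lum passed over all genes tested.

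Some lists outside the 4 were called under an alternative, by camera with the preset correlation at adjusted p from 9.48e-07 to 0.0479. Inflammatory cytokines were lower without control 1, without mutant 1 or with no low-count filter, niche factors without control 1 or with mixed cells, and hypoxia response genes with no low-count filter. Extracellular matrix and TGF-beta signalling were lower with mixed cells, and glycolysis was higher. Osteogenesis and Wnt signalling were higher with doublets kept or at resolution 2.0, interferon response without control 1, and cholesterol synthesis without control 1 or with no low-count filter. Cell cycle was higher without control 1 or mutant 2, with no low-count filter, with the stricter filter, at resolution 2.0 or with mixed cells. The respiratory chain was higher by limma-voom, without control 1, with mixed cells or without the low-UMI sub-cluster.

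Transcripts typical of neutrophils were more abundant in LepR-like cells of both mutants, while for those of red cells control 2 lay near the mutants. Neutrophil markers, such as S100a8 and Camp, made up 0.366% and 0.231% of LepR-like UMIs in the controls and 0.502% and 0.531% in the mutants. Erythroid markers made up 0.103% and 0.328% against 0.337% and 0.351%, so their group difference rests largely on control 1. By camera the neutrophil list (8 of 9 positive, median 0.85) had adjusted p = 8.81e-10 and the erythroid list (4 tested, median 0.73) adjusted p = 1.17e-05, and both had adjusted p = 0.154 with an estimated correlation. Adjusted over the list alone, 7 neutrophil and 2 erythroid markers were higher, while edgeR called 0 over all genes. The class's own markers did not move together (median -0.08, adjusted p = 0.441), nor did osteoblast-like (adjusted p = 0.663, with a negative median and a positive mean and test) or pericyte-like markers (adjusted p = 0.274). In the other direction, the stromal genes Sparc, Col1a1, Col1a2, Cxcl12 and Igfbp5 summed to 20.0 and 20.1 CPM in neutrophil-like cells of the controls and 49.1 and 35.8 CPM in the mutants. In T or NK-like cells the sum was 28.1 and 23.1 against 108 and 65.7 CPM. In progenitor-like cells the groups overlapped, at 24.3 and 14.4 against 54.7 and 16.8 CPM, and in erythroid-like cells, at 25.8 and 8.99 against 65.6 and 27.3 CPM, control 1 lay near mutant 2. In B lineage-like cells it was 32.4 and 22.2 against 81.7 and 42.0 CPM and in monocyte or macrophage-like cells 23.2 and 17.9 against 56.8 and 46.3. In basophil or mast-like cells it was likewise higher in both mutants than in both controls.

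Pooling LepR-like and osteoblast-like cells gave no called gene. Olfml3 had a log2 fold change of 1.74, Wif1, a secreted Wnt inhibitor, one of 1.53, and Comp, a cartilage and tendon matrix protein, one of 3.41. Vcan, a matrix proteoglycan, was at 1.92 and Cd52, a leukocyte surface protein, at 1.79. Lower values were -1.81 for Stat5a, -1.73 for Angptl1, -1.43 for the anticoagulant receptor Thbd, -1.27 for the Hedgehog receptor Ptch1 and -2.64 for Gm42679. None passed, and adjusted p was 0.315 for each. The edgeR count was 0 of 7192 genes, with 432 at an unadjusted p under 0.05, while DESeq2 called 3 and limma-voom 0. This pool moves with the proportion of osteoblast-like cells, which was 26.9% and 11.8% of mesenchymal cells in the controls and 33.0% and 33.6% in the mutants.

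LepR-like and osteoblast-like cells formed a larger share of kept cells in both mutants than in both controls, although the LepR-like intervals of control 2 and mutant 2 overlapped. With at most 5% mitochondrial UMIs the LepR-like shares overlapped themselves, at 0.467% and 0.769% against 1.27% and 0.698%, while osteoblast-like shares stayed apart, at 0.102% and 0.0699% against 0.588% and 0.276%. Without the low-UMI sub-cluster LepR-like cells numbered 25 and 62 against 72 and 52, or 0.350% and 0.717% against 0.717% and 0.634%, so mutant 2 lay below control 2. LepR-like cells were 0.532% (0.377 to 0.729) and 0.774% (0.601 to 0.982) of kept cells in the controls and 1.47% (1.25 to 1.73) and 0.890% (0.698 to 1.12) in the mutants. Osteoblast-like cells were 0.196% (0.107 to 0.328) and 0.104% (0.0476 to 0.197) against 0.727% (0.570 to 0.913) and 0.451% (0.318 to 0.621). The mixed sub-clusters made up 0.210% and 0.231% against 1.13% and 2.10%. In each of these the exact permutation p was 0.333, the smallest this design allows. On cell counts, edgeR called osteoblast-like cells (log2 fold change 1.98, adjusted p = 0.0182) and mixed cells (2.86, adjusted p = 0.000657) higher, but not LepR-like cells (0.85, adjusted p = 0.373). Within mesenchymal cells the LepR-like share was lower in the mutants by 13.95 percentage points, 66.7% against 80.6% (exact permutation p = 0.333). These shares depend in part on the sort. The split between LepR-like and osteoblast-like cells also depends on a naming rule set after the clusters were seen. That rule moved a sub-cluster from LepR-like to osteoblast-like, and no alternative without it was run.

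**Figure D2:**
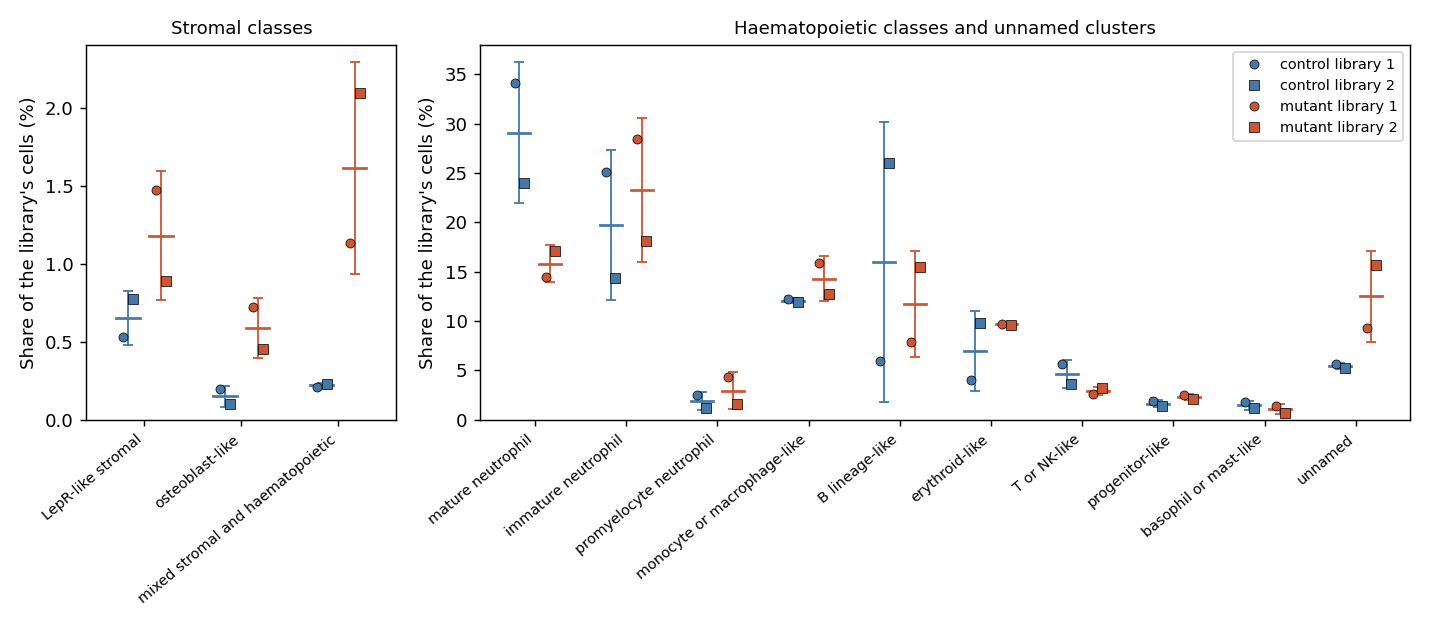
Share of each library's kept cells, in percent, with stromal classes in 1 panel and haematopoietic classes, neutrophils by stage, in another, and with points for libraries (circle 1, square 2), a short line for the group mean and whiskers for the SD of 2 libraries. LepR-like cells lie at 0.532% and 0.774% in controls and 1.47% and 0.890% in mutants, and B lineage-like cells range from 5.96% to 26.0%.

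Haematopoietic shares varied as much within as between groups for several classes. B lineage-like cells were 5.96% and 26.0% in the controls and 7.89% and 15.5% in the mutants, and neutrophil-like cells 61.8% and 39.6% against 47.2% and 36.9%. Erythroid-like cells were 4.07% and 9.85% against 9.73% and 9.63%, and basophil or mast-like cells 1.80% and 1.17% against 1.43% and 0.719%. Monocyte or macrophage-like cells were 12.2% and 11.9% against 15.9% and 12.7%, and progenitor-like cells 1.87% and 1.41% against 2.53% and 2.10%. T or NK-like cells were 5.64% and 3.68% against 2.64% and 3.24%. By edgeR on cell counts none of these 7 classes was called, with adjusted p from 0.504 to 0.689.

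In mature neutrophils, 24 genes were higher and 17 lower in the mutants of 8714 tested. Wfdc17, a WAP-domain secreted protein, rose from 130 ± 17 to 2116 ± 528 CPM (SD, n = 2), a log2 fold change of 4.03 (SE 0.26, adjusted p = 0.00131). Steap4, a metalloreductase, rose by 3.17 (SE 0.31, adjusted p = 0.0107), the lipopolysaccharide co-receptor Cd14 by 2.60, the interferon-induced Ifitm1 by 2.47 and the interleukin 13 receptor chain Il13ra1 by 1.71. Thbs1, a matrix glycoprotein, fell from 493 ± 248 to 52.3 ± 28.9 CPM, a log2 fold change of -3.23 (SE 0.45, adjusted p = 0.0299). Krt83, Lrmp, Ccno and Mylip, the last a ubiquitin ligase for the LDL receptor, fell by 2.28, 1.99, 1.74 and 1.42. Taken over all neutrophil-like cells, edgeR called 0 of 12082 genes, with 2602 at an unadjusted p under 0.05, while DESeq2 called 296 and limma-voom 0. In this class edgeR called 1931 with the replicate block, 1367 with no low-count filter, 451 at resolution 0.5, 341 with doublets kept and 15 with total counts only. Without control 1, control 2, mutant 1 or mutant 2 it called 42, 0 (935 at an unadjusted p under 0.05), 4 or 255.

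Some clusters of mature cells held unequal numbers of control and mutant cells. This restates the difference above, since the clusters were formed on the same expression values without batch integration. A cluster led by Wfdc17 and Ifitm1 held 90 and 70 control cells against 1246 and 1151 mutant cells. A pair of clusters with Thbs1 among their leading genes held 691 and 577 against 37 and 38 cells, and 809 and 600 against 55 and 55. An unnamed cluster resembling neutrophils, with Il1b and Wfdc17 among its leading genes, held 174 and 137 against 398 and 767 cells, and with it the calls in mature neutrophils numbered 93. The share of mature neutrophils was 34.1% and 24.0% in the controls and 14.5% and 17.1% in the mutants (exact permutation p = 0.333). With at most 5% mitochondrial UMIs the groups overlapped, at 28.6% and 23.1% against 19.1% and 23.8%, as with the stricter filter, at 12.9% and 10.2% against 6.26% and 17.6%. With the unnamed cluster they overlapped too, at 36.6% and 25.6% against 18.5% and 26.5%.

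Interferon response genes were higher in mature neutrophils of the mutants by camera (25 of 26 positive, median 0.60, adjusted p = 1.42e-15), but not with an estimated correlation (adjusted p = 0.633), with the guanylate-binding protein Gbp2 at 1.82, the nucleic acid sensor Zbp1 at 1.64 and Oasl2 at 1.12. Adjusted over the list alone, 12 of them were higher, and over all genes 1, Gbp2. Mitochondrially encoded genes were higher (13 of 13 positive, median 0.87, adjusted p = 1.49e-12), with 10 adjusted over the list alone, and had adjusted p = 0.633 with an estimated correlation. Cell cycle (adjusted p = 3.24e-07), cholesterol synthesis (0.00224), ribosomal proteins (0.0131) and the unfolded protein response (0.0291) were also higher, and angiogenic factors, which include Thbs1, lower (0.00363). With an estimated correlation these had adjusted p = 0.768, 0.779, 0.848, 0.633 and 0.633. Splitting neutrophils by stage was chosen after the data were seen, and leaving out control 1, control 2, mutant 1 or mutant 2 gave 218, 147, 112 or 312 calls, with 41, 39, 41 and 39 of the 41 among them. Of the 41, 13 were called with the stricter filter, 15 by limma-voom, 26 at resolution 2.0, 27 with doublets kept, 33 with equal cells, 34 with at most 5% mitochondrial UMIs and 37 at resolution 0.5.

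**Figure D3:**
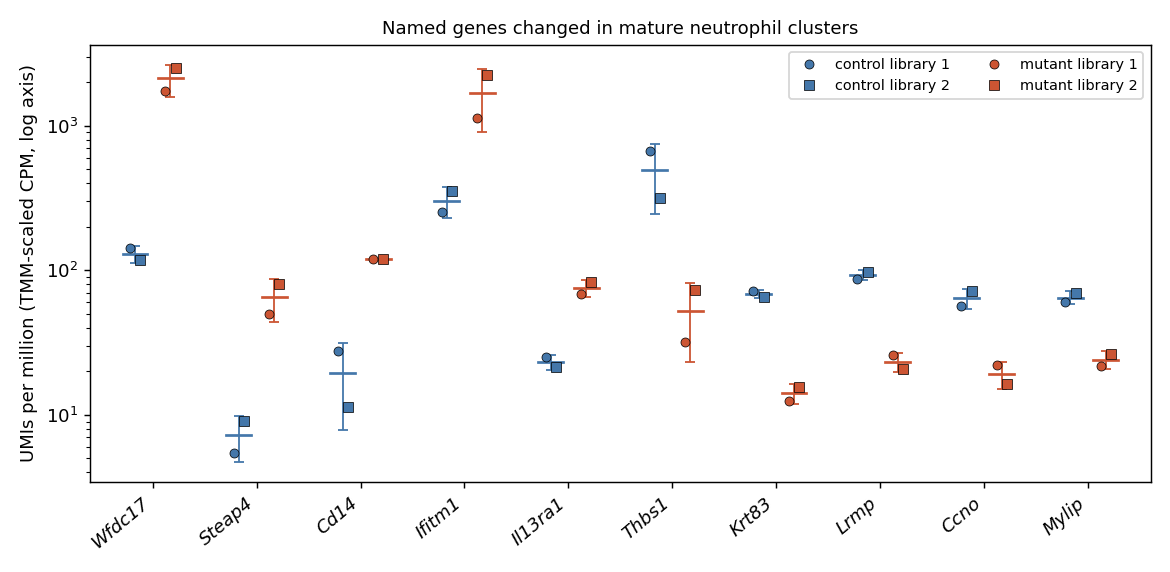
Normalised expression in CPM, on a log axis, of the named genes in mature neutrophil clusters of each library, with points for libraries (circle 1, square 2), a short line for the group mean and whiskers for the SD of 2 libraries. Wfdc17 averages 130 CPM in controls and 2116 CPM in mutants, and Thbs1 493 and 52.3 CPM.

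In T or NK-like cells, 14 genes were higher and 6 lower in the mutants of 9228 tested. Interferon-induced Ifitm3 rose from 67.4 ± 3.47 to 232 ± 50.02 CPM (SD, n = 2), a log2 fold change of 1.77 (SE 0.20, adjusted p = 0.0216). Wfdc17 rose by 2.60, the lipoprotein Apoe by 1.92, fibronectin (Fn1) by 1.91 and the calmodulin-binding Nrgn by 1.56. Wfdc17 also rose in mature neutrophils. Neutrophil markers made up a larger median share of UMIs in T or NK-like cells of both mutants, as given below. Whether free neutrophil RNA contributes to the Wfdc17 rise was not tested. The lymph node homing receptor Ccr7 fell by 1.88 (79.8 ± 33.4 to 21.3 ± 4.56 CPM, adjusted p = 0.0402), Dapl1 by 1.65, the CD8 beta chain Cd8b1 by 1.41 and the T cell transcription factor Lef1 by 1.24. Fam169b fell by 1.995. The T cell cluster of this class held 310 and 258 cells in the controls and 193 and 173 in the mutants, and the NK cluster 93 and 60 against 72 and 93, so the mixture differed.

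Cell cycle genes were higher in T or NK-like cells by camera (20 of 20 positive, median 1.01, adjusted p = 3.53e-15), but not with an estimated correlation (adjusted p = 0.423), with 11 higher adjusted over the list alone, among them Stmn1 at 1.27, Cdc20 at 1.63 and Ccna2 at 1.70. The respiratory chain list was higher (adjusted p = 2.35e-08) and the Wnt list, which holds the T cell factors Lef1 and Tcf7, was lower (0.000931). With an estimated correlation these had adjusted p = 0.457 and 0.394. Osteogenesis genes (Sparc at 1.99 and Ibsp) and adipogenesis genes (Apoe) were higher at adjusted p = 0.00102 each (0.394 with an estimated correlation), in a class where the stromal transcript sum was also higher in both mutants. Interferon response (adjusted p = 0.00663), unfolded protein response (0.00591) and antioxidant genes (0.0134) were higher and TGF-beta signalling lower (0.041). These 4 lists also had adjusted p = 0.394 with an estimated correlation. With at most 5% mitochondrial UMIs edgeR called 0 genes in this class (1050 at an unadjusted p under 0.05), with doublets kept or equal cells 1 and with the stricter filter 9, while at 10% DESeq2 called 30 and limma-voom 2. Without control 1, control 2, mutant 1 or mutant 2 there were 111, 644, 19 or 37 calls, with 20, 20, 11 and 12 of the 20 among them.

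Basophil or mast-like cells had 21 genes higher and 1 lower in the mutants of 7121 tested. The higher genes included S100a8, S100a9, Camp and Ngp of the neutrophil marker list. Neutrophil RNA in these droplets, free or from doublets, may therefore contribute to the rises below, which was not tested. Chil3, a chitinase-like protein, rose from 74.5 ± 3.69 to 681 ± 6.91 CPM (SD, n = 2), a log2 fold change of 3.19 (SE 0.22, adjusted p = 0.000103), Lrg1 by 3.57, Ifitm6 by 3.15, the iron-sequestering lipocalin Lcn2 by 2.78 and the neutrophil antigen Cd177 by 2.53. The chemokine Ccl4 fell from 715 ± 147 to 196 ± 6.93 CPM, a log2 fold change of -1.87 (adjusted p = 0.00535). The immediate early genes Fosb at -1.10 and Dusp1 at -1.99, the cytokine Osm at -1.54 and the G protein regulator Rgs1 at -1.44 did not pass, with adjusted p from 0.0773 to 0.0965. By camera, immediate early genes were lower (12 of 17 negative, adjusted p = 3.25e-06), with 6 lower adjusted over the list alone, and the respiratory chain (6.26e-06) and ribosomal proteins (0.000561) were higher. All 3 had adjusted p = 0.778 with an estimated correlation. Without control 1, control 2, mutant 1 or mutant 2 there were 12, 36, 72 or 105 calls, with 8, 20, 22 and 22 of the 22 among them, and with doublets kept, equal cells or the stricter filter 3, 8 or 14, with 3, 8 and 11 among them.

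In monocyte or macrophage-like cells the 1 called gene of 11466 was Ear1 (ENSMUSG00000072601), an eosinophil-associated ribonuclease. It had 0 UMIs in both controls, which allows up to 0.310 and 0.286 CPM of the class total from 3 counts, and 481 and 350 UMIs in the mutants, or 32.2 and 28.3 CPM after TMM scaling (adjusted p = 0.012). Ear1 belongs to a family of near-identical genes, so its count is uncertain, and reads shared with its relatives were not examined. Arsb, a lysosomal sulfatase, had a log2 fold change of 1.32 (adjusted p = 0.0944) and Cd63, a lysosomal tetraspanin, 1.20 (adjusted p = 0.138), and neither passed. With the clusters led by plasmacytoid dendritic cell genes, left out after the clusters were seen, the class had 0 calls. DESeq2 called 23 genes and limma-voom 1, and edgeR 237 with no low-count filter and 216 with the replicate block. Leaving out control 1, mutant 1 or mutant 2 gave 2, 75 or 36 calls, and Ear1 was among them each time.

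Erythroid-like cells had 0 calls by edgeR of 10494 genes (455 at an unadjusted p under 0.05, 8 by DESeq2, 0 by limma-voom). Among genes that did not pass, the granule protease Ctsg was at 2.15 (adjusted p = 0.303) and the purine nucleoside phosphorylase Pnp2 at -1.36 (adjusted p = 0.109). Pnp, which overlaps Pnp2 on chromosome 14, was at -0.91 (adjusted p = 0.954). B lineage-like cells had 0 calls by edgeR of 11076 (431 unadjusted, 12 by DESeq2, 0 by limma-voom), and progenitor-like cells 0 of 10194 (503 unadjusted, 6 by DESeq2, 1 by limma-voom). Leaving out control 1, control 2, mutant 1 or mutant 2, edgeR called 48, 37, 76 or 18 genes in erythroid-like cells, 167, 4, 20 or 23 in B lineage-like cells and 88, 61, 6 or 16 in progenitor-like cells. With no low-count filter it called 108, 152 and 71 in these classes, and 5 in erythroid-like cells with total counts only. With the replicate block it called 50, 48 and 66.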

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

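The alternatives with mixed cells, without the LepR-like sub-cluster of lowest UMI count and with the unnamed neutrophil cluster, and the stage split, were chosen after the data were seen, as was LepR-like as the class standing for the shares. Causes were not tested except where the alternative removes genes, cells or libraries by construction. A fit without a library leaves an arm with 1 sample, assumed to vary like the other arm. The osteoblast-like class and its comparison with LepR-like cells were not run, nor was camera under DESeq2.

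In LepR-like cells the 6 calls became 3 with total counts only, 2 with DESeq2, 3 with limma-voom, 32 with no low-count filter, 1 with at most 5% mitochondrial UMIs, 1 with the stricter cell filter, 2 with doublets kept, 1 with equal cells, 177 with mixed cells and 1 without the low-UMI sub-cluster. Without 1 library they ranged from 18 (mutant 1) to 43 (control 1), with 31 without control 2 and 25 without mutant 2. Olfml3 kept an adjusted p under 0.05 in each of these and at RLE factors and both resolutions, the largest being 0.0249 with equal cells. With the replicate block, given below, 0 genes were called, so Olfml3 was lost as well. Epas1 turned from 0.15 to -0.35 with mixed cells, neither passing.

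The pooled mesenchymal count of 0 (edgeR, 432 at an unadjusted p under 0.05, limma-voom 0) became 3 with DESeq2, 110 with no filter, 3 with the stricter filter and 1 with mixed cells, and ranged from 6 (without mutant 1) to 60 (without control 2), with 51 without control 1 and 15 without mutant 2. The 41 calls in mature neutrophils became 95 with DESeq2, 15 with limma-voom, 412 with no filter, 66 with at most 5% mitochondrial UMIs, 17 with the stricter filter and 93 with the unnamed cluster, ranging from 112 (without mutant 1) to 312 (without mutant 2), with 218 and 147 without controls 1 and 2. For genes changed in other classes, summed, 43 calls became 70 with total counts, 395 with DESeq2, 19 with limma-voom, 2445 with no filter, 21 with at most 5% mitochondrial UMIs, 25 with the stricter filter, 350 with doublets kept, 494 at resolution 0.5 and 11 with equal cells, ranging from 272 (without mutant 1) to 783 (without control 2), with 470 without control 1 and 490 without mutant 2. At resolution 0.5 progenitor-like cells formed no class.

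The 4 lists called in LepR-like cells became 8 with no filter, 7 at resolution 2.0, 2 with equal cells, 9 with mixed cells, 0 with an estimated correlation and 0 with fry, ranging from 1 (without control 2) to 10 (without control 1). Markers of other cell types called there, 0 by edgeR, became 4 with no filter and 9 with mixed cells, and 0 (without mutant 1) to 6 (without control 1), with 5 without control 2 and 3 without mutant 2. The LepR-like share, higher in mutants by 0.53 percentage points of all cells, was lower as a share of mesenchymal cells only, at -13.95 points, where osteoblast-like cells rose from 14 and 9 to 73 and 37. Of all cells, the LepR-like difference was 0.142 points without the low-UMI sub-cluster. In the class shares of mature neutrophils, whose alternatives were chosen after the data were seen, the difference of -13.3 points turned to 0.416 with the stricter filter (the cause was not tested). Cd93 in promyelocyte clusters, not passing, turned from -0.74 to 0.13 at resolution 0.5 (the cause was not tested). Of 35 named genes that passed, RLE factors kept 35, DESeq2 30, limma-voom 22, the 5% limit 19, the stricter filter 18, doublets kept 17, equal cells 20 and leaving out a library 28 to 31.

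With the replicate block, immediate early genes had adjusted p = 0.0627 in LepR-like cells, and counts were 0 for LepR-like (381 at an unadjusted p under 0.05, with Olfml3 in LepR-like stromal cells at 2.44 and adjusted p = 0.275), 27 for pooled mesenchymal, 210 for mature neutrophils, 1327 for immature neutrophils (8 without it) and 2422 for genes changed in other classes. Of the last, 1931 were in neutrophil-like, 50 in erythroid-like, 48 in B lineage-like and 66 in progenitor-like cells, each with 0 calls without the block. Within each class, the difference between the control libraries was correlated over genes with that between the mutant libraries, both taken in number order. The correlation was positive in every class, at 0.101 to 0.365, so libraries of the same number tended to depart from their group alike. This similarity rests on 2 pairs and cannot be told from chance. Whole-library counts also differed least between libraries of the same number. Chi-square per degree of freedom was 109 and 123 there, against 191 to 387 for other pairs. These whole-library sums also move with the mixture of cell classes in a library, which was not separated here. The labels give no shared animal, litter or day, so libraries were not treated as paired, but a shared batch was not excluded. The results without the block depend on this choice.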

Other observations

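The tests of the stress lists, of free RNA and of the region around Epas1, and the split of neutrophils by stage, were chosen after the results they bear on were seen.

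In immature neutrophils, 5 genes were higher and 3 lower in the mutants of 10455 tested by edgeR. Ms4a3, a marker of granulocyte and monocyte precursors, rose by 1.12 on the log2 scale (57.6 ± 3.50 to 126 ± 9.57 CPM, SD, n = 2, adjusted p = 0.0489), while Tex15 fell by 1.31 (adjusted p = 0.04) and Lrmp by 1.27 (adjusted p = 0.0287). Thbs1 at -2.07 (adjusted p = 0.0518), the kinase-like Trib1 at -1.67 and the nucleotide kinase Nme2 at 1.26 (both adjusted p = 0.0563) did not pass. Without control 2 there were 0 calls by edgeR, with 1512 genes at an unadjusted p under 0.05, and at resolution 0.5 also 0, with 1165. With all libraries DESeq2 called 162 and limma-voom 7. The 8 calls became 869 with no low-count filter, 320 with at most 5% mitochondrial UMIs, 22 with total counts only, 18 with the stricter filter and 14 with equal cells, of which 8, 7, 7, 6 and 8 were among the 8. Without control 1, mutant 1 or mutant 2 there were 7, 156 or 128 calls, and 3, 8 and 8 of the 8 were among them. Promyelocyte clusters, marked by the granule proteins Elane and Mpo, had 0 calls by edgeR of 10026 genes (456 unadjusted, 7 by DESeq2, 0 by limma-voom), 79 with no low-count filter and 2, 0 (306 unadjusted), 42 or 36 without control 1, control 2, mutant 1 or mutant 2, with Lcn2 at 1.19 and Cd93 at -0.74, neither passing.

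In B lineage-like cells Igha, the constant region of IgA, stood at 15.4 and 2.84 CPM in the controls and 605 and 3392 CPM in the mutants, a log2 fold change of 8.01 that did not pass (adjusted p = 0.413). The UMIs were 43 and 34 against 2480 and 25684. How many cells carried them was not examined, so a change across the class is not shown. The galectin Lgals3 at 1.32 (adjusted p = 0.413) and Mta3, a chromatin factor of B cells, at -1.18 (adjusted p = 0.413) did not pass either. In progenitor-like cells the calcium-binding S100a6 was at 1.19 (adjusted p = 0.152), the stem cell antigen Ly6a at 1.33 and the chemokine Ccl9 at -0.90, none passing. Clusters led by plasmacytoid dendritic cell genes such as Siglech held 173 and 217 cells in the controls and 341 and 357 in the mutants, and 54 and 78 against 171 and 77. They were in no comparison.

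Immediate early and heat shock genes were lower in LepR-like cells of the mutants by camera with its preset correlation, with medians of -0.32 and -0.49, but both calls were lost with an estimated correlation (adjusted p = 0.733). Immediate early genes were also not called with the stricter filter (0.328), at resolution 0.5 (0.0856), without the low-UMI sub-cluster (0.639) or with equal cells (0.935, upward). Nor were they called without control 2, with the replicate block or with mixed cells, where the test turned upward too. For loss of Epas1 acting only within mesenchymal cells, a first test pooled both lists and found 0 of 7 haematopoietic classes with a median as low as in LepR-like cells, and was replaced by a test of each list, to which the estimated correlation was added later. Immediate early genes were as low in 3 of the 7 (basophil or mast-like -0.56, neutrophil-like -0.48, monocyte or macrophage-like -0.38), and each of these 3 was called lower with the preset correlation. In all they were called lower in 4, at adjusted p from 0.735 to 0.778 with an estimated correlation. Heat shock genes were as low in 0 and called lower in 3, at 0.527 to 0.735. The condition added later could hardly be met, since with an estimated correlation even the LepR-like calls were lost. The test therefore decides nothing about that explanation for either list. A difference in handling or batch shared by all cells of a library cannot be told apart from genotype, since both medians lay below 0 in 5 of the 7 classes and the labels give no batch.

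Neutrophil markers were higher in LepR-like cells of the mutants, as a median of 0.394% and 0.219% of a cell's UMIs in the controls against 0.441% and 0.546% in the mutants. Free RNA taken up by all droplets may contribute: the medians were higher in both mutants in 3 of 3 classes, with B lineage-like cells at 0.376% and 0.248% against 0.403% and 0.484% and T or NK-like cells at 0.353% and 0.209% against 0.402% and 0.392%, although the classes share the same libraries. A few LepR-like droplets that also hold a neutrophil stay open too: they would leave the medians of the groups overlapping, and the lowest mutant median exceeded the highest control median by 0.0472 percentage points, less than the 0.174 between the controls. A first test, the share of cells with an S100a8 UMI, was dropped because it was at least 93.2% in every library of all 3 classes. Whether genotype changed the amount of free RNA was not tested.

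A few genes near Epas1 on chromosome 17 had an unadjusted p under 0.05 in the same direction in at least 3 of the 7 haematopoietic classes, lineages outside the mesenchyme that the labels give for Prx1-Cre. These were Haao, Mta3, Prkd3 and Thumpd2, with Haao at 10.6 and 11.3 CPM in neutrophil-like cells of the controls and 2.12 and 2.14 CPM in the mutants (log2 fold change -2.36, adjusted p = 0.0852) and at -1.91 in mature neutrophils (adjusted p = 0.0287). A strain haplotype carried along with the floxed allele could give this, and within 10 Mb of Epas1 4 of 56 genes (7.14%) met the criterion against 342 of 10966 elsewhere (3.12%, odds ratio 2.39, Fisher exact p = 0.0984). On the rest of the chromosome the share was 4.30%. The test had few genes, the pattern was found by looking at the genes first, and the explanation stays open. Regions of other chromosomes were not examined in this way.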
